A study of Mus musculus with 6 samples.

How the data were processed

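RNA was measured in cultured primary keratinocytes from the epidermis of mice at postnatal day 2, in 3 wild type libraries (replicates 13, 14 and 15) and 3 libraries of the p63 alphaKO genotype (replicates 9, 10 and 11). Per the series description, epidermis was lifted off the dermis with Dispase overnight and dissociated with Accutase. Per the labels' protocols, the cells grew to confluence over 5 to 6 days at 0.05 mM calcium with 4% chelated serum and 2.5 ng/mL EGF, and RNA was purified on columns and sequenced as 3' digital gene expression. Such an assay counts reads near the 3' ends of transcripts, so it gives a level per gene and seldom per isoform. The sources used here do not say which part of Trp63 the p63 alphaKO genotype lacks, nor whether the libraries of a group come from separate animals or litters. The groups share no replicate numbers, so no paired analysis was made.

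STAR, HTSeq and the mouse build mm10 are named in the submitters' processing notes, with no roles or options. Their versions, the gene annotation, the filters and any use of molecular identifiers are not given in the sources used here. The deposited values are CPM (counts per 1000000 reads), with 2 decimals, as read from the table itself: each of the 6 columns sums to between 999047 and 999508, and 100% of the values above 0 lie within 0.1 read of a whole multiple of the value of 1 read in that library. Per the labels, each column is 1 library, and all 6 columns were used. Dividing by the value of 1 read gave back 1699716 to 3215333 reads per library over 30349 genes listed, of which 15588 had a read in any library. Without molecular identifiers, reads are not independent molecules, so intervals on reads cover counting error alone.

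Genes with a mean of at least 1 CPM over the 6 libraries were tested, 11716 in all. The test was limma 3.58.1 in R 4.3.3, with a mean-variance trend (eBayes), on log2(CPM + 1) with no further scaling, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A log2 fold change is p63 alphaKO minus wild type, and SE is its moderated standard error from limma. Adjusted p-values are limma's unless another tool is named. Rate ratios of genes with 1 to 3 reads in a group come from the reads pooled over each group, with an exact 95% interval. The genes named are Trp63, then up to 10 genes per direction with the largest log2 fold change among those past the threshold whose libraries did not overlap between the groups, leaving out predicted gene models and pseudogenes. Where fewer than 10 passed, the genes of smallest p filled each direction up to 10, as values. From each list, up to 4 members past the threshold were named, or 2 of smallest p where none passed; a gene that the rule names is in some lists not reported here. Members of the cell type, sex and handling lists may be named by their level in each library.

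The 40 gene lists were basal layer, spinous differentiation, cornified envelope and late differentiation, epidermal barrier lipid, desmosome, tight and adherens junction, reported p63 target genes, epidermal transcription factors, the p53 family, simple and mucosal keratins, wound and alarm, interferon response, mitosis, DNA replication, p53 target genes, senescence, mesenchymal and migration genes, hemidesmosome and basement membrane, the Notch, BMP and TGF-beta, and Wnt pathways, FGF and EGF receptors and ligands, cholesterol synthesis, glycolysis and hypoxia, oxidative stress, unfolded protein stress, class I antigen presentation, oxidative phosphorylation, mitochondrially encoded genes, early response genes of cell handling, sex-linked genes, and markers of fibroblasts, melanocytes, immune and Langerhans cells, endothelium, Merkel cells, hair follicle, sebaceous gland, muscle and erythroid cells. Of their 725 genes, 8 are not listed in the table under the symbols used. The lists with at least 3 tested members, 37 of them, were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list moves at all, stand beside it. Tests, lists, the rule for named genes and most alternatives were fixed before the data were examined.

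Coordinates are from GENCODE vM21 on GRCm38 (mm10), in which 28516 symbols of the table were found once. The test was tried on 5 simulated data sets of this comparison, each with 11716 genes. In each, 200 genes were changed, drawn from those with a mean of at least 5 CPM. Recovery was 4.4% of genes changed 1.5-fold, 23.6% at 2-fold, 90% at 4-fold and 99.2% at 8-fold, and 38 of 581 calls were false. Recovery of lower genes was not simulated. Counts were drawn independently for each gene, so differences between libraries that many genes share were not simulated, and real recovery may be lower. Alternatives were pseudocounts of 0.5 and 5, no filter and a minimum mean of 5 CPM, quantile, equal-total and TMM scaling, no trend, robust moderation, array weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, sex as a covariate, and each library left out in turn. Added after seeing the data were thinning to equal depth (1699716 reads, 20 draws), 1 surrogate variable (sva 3.50.0), and leaving out wild type replicate 15 and p63 alphaKO replicate 11 together.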

Results

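Gene expression was profiled by 3' digital sequencing in 6 cultures of mouse epidermal keratinocytes, 3 wild type and 3 p63 alphaKO. The protein p63, encoded by Trp63, is a transcription factor needed to form stratified epithelia, and its alpha isoforms carry the long C-terminal end. Mutations in that end cause AEC syndrome, a disorder of skin, nails and facial clefts. The wild type libraries held 3180984, 3215333 and 3146374 reads (replicates 13, 14 and 15) and the p63 alphaKO libraries 2188705, 2999246 and 1699716 reads (replicates 9, 10 and 11), and levels are in CPM, counts per 1000000 reads of a library. At least 1 read was seen for 12545 to 13418 genes per library. A gene listed at 0 CPM may have up to 0.93 CPM in the deepest library and 1.76 CPM in the shallowest, the level of 3 reads.

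The comparison asks how keratinocytes labelled p63 alphaKO differ from wild type keratinocytes in gene expression. Trp63 itself (chromosome 16, 25683763 to 25892102, plus strand) was read at 38.0, 53.2 and 48.9 CPM in the wild type libraries and at 49.8, 59.3 and 57.0 CPM in the p63 alphaKO libraries, a log2 fold change of 0.25 (SE 0.26, n = 3 per group, limma adjusted p = 0.926). This level does not check the genotype. In the annotation 4 of the 8 protein-coding Trp63 transcripts end in an exon starting at 25889008, and a 3' value per gene does not tell which transcript, or which part of the gene, the reads came from.

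Krt1 fell in p63 alphaKO keratinocytes, and Cdkn1c, Sncg, Fut9 and Ifitm3 rose. Folds are those fitted on log2(CPM + 1), so they differ somewhat from ratios of the mean CPM. Krt1, the keratin that pairs with Krt10 in the suprabasal layers of the epidermis, was 5.43-fold higher in wild type, at 278.5 ± 110.7 CPM (SD, n = 3) against 51.0 ± 21.9 CPM (SD, n = 3). Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, was 7.19-fold higher in p63 alphaKO, at 34.7 ± 4.83 CPM against 4.30 ± 2.24 CPM. Sncg, encoding gamma-synuclein, was 4.08-fold higher, at 268.7 ± 146.5 CPM against 61.2 ± 22.1 CPM. Ifitm3, an interferon-inducible membrane protein that restricts virus entry, was 2.46-fold higher, at 1394 ± 253 CPM against 566.6 ± 93.3 CPM. Fut9, a fucosyltransferase that makes the Lewis x glycan, had 94 reads in the p63 alphaKO libraries and 3 in the wild type libraries, a rate ratio of 43.4 (exact 95% interval 14.4 to 214). This interval covers counting error on the pooled reads, not variation between libraries.

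**Figure D1:**
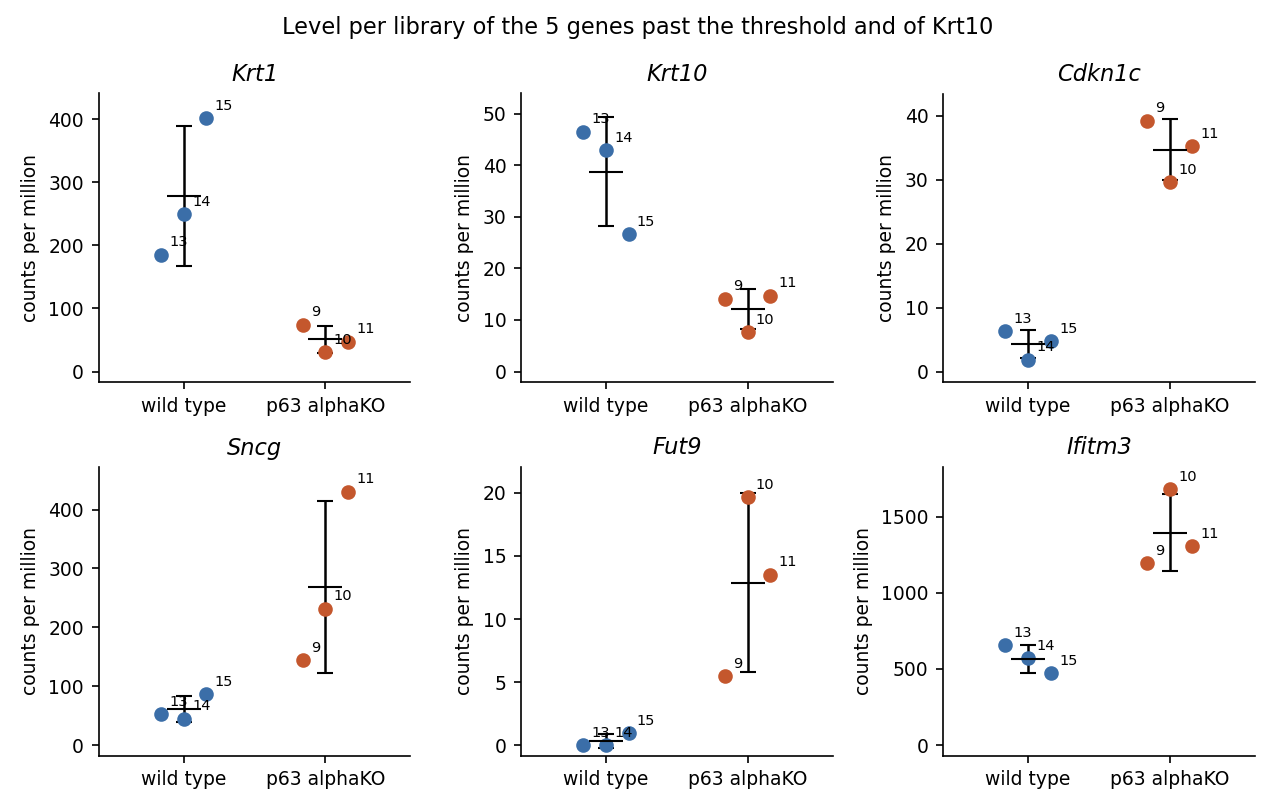
Level of Krt1, Krt10, Cdkn1c, Sncg, Fut9 and Ifitm3 in CPM, 1 point per library labelled with its replicate number, for wild type (blue) and p63 alphaKO (orange); bars are the mean and SD of 3 libraries. The groups do not overlap for any of the 6 genes: Krt1 spans 185.38 to 400.87 CPM in wild type and 30.99 to 74.43 CPM in p63 alphaKO, and Krt10, which did not pass the threshold, is drawn beside it.

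The log2 fold changes were -2.44 for Krt1 (SE 0.32, limma adjusted p = 0.00686), 2.85 for Cdkn1c (SE 0.39, 0.00686), 2.03 for Sncg (SE 0.34, 0.0415), 3.32 for Fut9 (SE 0.55, 0.0415) and 1.30 for Ifitm3 (SE 0.22, 0.0479). The fitted value for Fut9, at 0 reads in 2 wild type libraries, moves with the pseudocount and the tool, from 1.67 with a pseudocount of 5 to 5.34 by DESeq2. In GRCm38 coordinates, all on the minus strand, Krt1 lies on chromosome 15 (101845426 to 101850794), Cdkn1c and Ifitm3 on chromosome 7 (143458339 to 143461050 and 141009586 to 141010770), Sncg on chromosome 14 (34370274 to 34374789) and Fut9 on chromosome 4 (25609332 to 25800244). These 5 genes, 4 higher and 1 lower and each changed at least 2-fold, were those past the threshold among 11716 tested. edgeR called 2 of them (Cdkn1c and Krt1), and DESeq2 called all 5 among 18 genes. At an unadjusted p under 0.05 there were 745 genes, 353 higher and 392 lower, against 586 for independent tests with no effect, and other splits of the same 6 libraries gave 194 to 1248. The groups did not overlap for 1352 genes, 11.5% of those tested, where chance gives 10%.

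Krt1 passed in each of the 6 fits that left out 1 library (adjusted p 0.00395 to 0.0416). Cdkn1c passed in 5 of the 6, with 0.0661 without p63 alphaKO replicate 9. Sncg did not pass without wild type replicate 13 (0.362) or 14 (0.444) or without p63 alphaKO replicate 10 (0.0709). Fut9 did not pass without wild type replicate 13 (0.224) or 14 (0.307), nor without p63 alphaKO replicate 10 (0.228) or 11 (0.0720). Ifitm3 passed without p63 alphaKO replicate 11 (0.00986), and not without wild type replicate 13 (0.224), 14 (0.444) or 15 (0.197) or p63 alphaKO replicate 9 (0.101) or 10 (0.174). The number of genes called was 2 without wild type replicate 13 or 14, 3 without p63 alphaKO replicate 10 and 13 without p63 alphaKO replicate 11.

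The next genes by p did not pass (adjusted p 0.286 to 0.320). The libraries of the groups did not overlap for any of them, which picking genes by small p favours. Krt10, the partner of Krt1, was at 38.7 ± 10.6 CPM in wild type and 12.2 ± 3.92 CPM in p63 alphaKO (log2 fold change -1.60). Krt15, a keratin of basal and hair follicle stem cells, was at 14.2 ± 5.06 and 2.86 ± 1.75 CPM (-2.02), and Sprr2a3, a cornified envelope gene whose near-identical copies can share its reads, at 170.3 ± 38.6 and 62.3 ± 29.1 CPM (-1.55). On the same side stood the protease Adamts1 (-2.36), the protease inhibitor Timp3 (-1.32), the guanine nucleotide exchange factor Net1 (-1.17), the spliceosome gene Snrpa1 (-1.11), and the muscle genes Ttn (-3.66) and Acta1 (-3.02). Adamts1 was at -1.48 without p63 alphaKO replicate 11, and Ttn at -2.41 and Acta1 at -1.86 without wild type replicate 15. On the other side stood Cbr2 (1.25), the glutamate receptor Grm4 (2.32), the peptide transporter Slc15a2 (1.44), the ubiquitin ligase gene Fbxo32 (1.29) and Ankk1 (1.70). Mmp9, a gelatinase, had 36 reads in p63 alphaKO and 1 in wild type, a rate ratio of 49.9 (exact 95% interval 8.40 to 2020). That interval covers counting error on the pooled reads, not variation between libraries.

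Genes of the spinous layer fell as a list, with 13 of 17 tested members lower and a median log2 fold change of -0.34 (camera adjusted p = 1.04e-05). With an estimated correlation between genes the adjusted p was 0.234. Krt1 passed over all genes, and 5 members passed when adjusted over the list alone: Krt1, Krt10, Calm4, Lgals7 and Calml3. Calm4, a calcium-binding protein of differentiating keratinocytes, was at 1575 ± 121 CPM in wild type and 918 ± 261 CPM in p63 alphaKO, and Lgals7 at 1189 ± 131 and 732 ± 155 CPM. The list median was -0.18 without wild type replicate 14 and -0.21 without p63 alphaKO replicate 11.

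Late differentiation and its regulators were lower as lists too, in a way that rested on single libraries. The cornified envelope list had 24 of 29 members lower and no member past the threshold (median -0.32, camera adjusted p = 3.99e-04, and 0.571 with an estimated correlation). Rptn (-1.86) and Flg2 (-1.42) overlapped between the groups. Flg2 was at 31.66 CPM in p63 alphaKO replicate 10, and Rptn at 27.32 CPM in wild type replicate 15 against 3.77 and 6.22 CPM in replicates 13 and 14. The camera adjusted p of the list was 0.10 without p63 alphaKO replicate 9 (median -0.11) and 0.104 without replicate 11 (-0.12). The list median was -0.54 without replicate 10. The epidermal transcription factors had 27 of 31 members lower (median -0.16, camera adjusted p = 4.89e-04; adjusted p = 0.571 with an estimated correlation). Msx2, a homeobox gene of hair follicle and epidermis, at 12.1 ± 2.81 CPM in wild type and 2.55 ± 2.03 CPM in p63 alphaKO, was the member that passed adjusted over the list alone, and Barx2 stood at -0.68. Without p63 alphaKO replicate 11 this list had an adjusted p of 0.403 and a median of 0.01, and the median was -0.29 without wild type replicate 15, -0.27 without p63 alphaKO replicate 9 and -0.26 without replicate 10.

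Basal and adhesion genes showed no called change as lists. Krt5 and Krt14, the basal keratins, were at 10622 ± 297 and 13349 ± 1014 CPM in wild type and 9710 ± 1532 and 13252 ± 2514 CPM in p63 alphaKO. The basal layer list had 9 of 17 members lower (median -0.03, camera adjusted p = 0.955, with camera's direction upward). Krt15 passed adjusted over that list alone. Reported p63 target genes had 23 of 33 lower (median -0.08, adjusted p = 0.0750), with Hes1 at -0.62 and Jag2 at -0.79. The desmosome list had 13 of 16 lower (-0.16, 0.0886; Dsc2 at 0.79, Dsg1a at -0.64), and barrier lipid genes 13 of 20 (-0.19, 0.0775; Alox12b at -0.91, Sdr9c7 at -0.75). Tight and adherens junction genes had 11 of 18 lower (-0.12, 0.496), where Ctnnd1 (-1.02) passed adjusted over the list alone and Cldn4 stood at 0.41. Hemidesmosome and basement membrane genes had 12 of 22 higher (0.05, 0.147; Lamb1 at 0.83). Simple and mucosal keratins had 3 of 5 lower (-0.23, 0.348; Krt4 at -0.95, Krt80 at -0.46), and the p53 family had 2 of 3 higher (0.25, 0.535; Trp73 at 0.60).

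**Figure D2:**
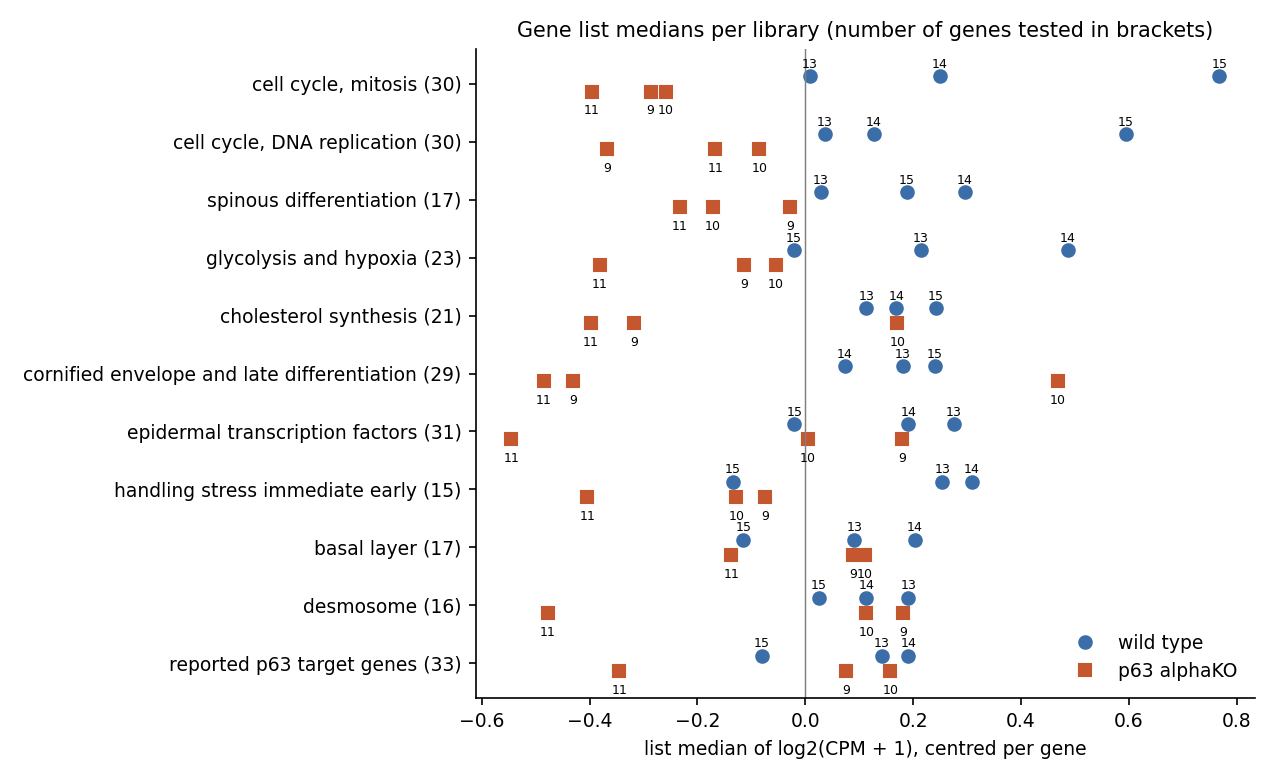
Median of log2(CPM + 1) over the tested members of each gene list shown, each gene centred on its mean over the 6 libraries. Wild type is drawn as blue circles and p63 alphaKO as orange squares, with replicate numbers. The lists shown are the called lists other than muscle, with the basal layer, desmosome and reported p63 target lists beside them. The mitosis list has medians of 0.01 to 0.77 in wild type and -0.40 to -0.26 in p63 alphaKO, while p63 alphaKO replicate 11 is lowest for the epidermal transcription factors at -0.55.

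Cell division genes were lower in p63 alphaKO as lists. All 30 mitosis genes lay lower (median -0.68, camera adjusted p = 9.21e-18; adjusted p = 0.435 with an estimated correlation). No member passed over all genes, and 6 passed adjusted over the list alone: Ccna2, Cdc20, Racgap1, Tpx2, Cenpa and Prc1. Ccna2, encoding cyclin A2, was at 40.8 ± 14.0 CPM in wild type and 15.9 ± 0.535 CPM in p63 alphaKO, and Cdc20, an activator of the anaphase-promoting complex, at 122.1 ± 24.5 and 65.8 ± 6.59 CPM. The DNA replication list had 26 of 30 members lower (median -0.49, camera adjusted p = 7.90e-09; adjusted p = 0.435 with an estimated correlation), with Mcm2 at -1.01 and Mcm4 at -0.92, helicase subunits, and no member past the threshold over all genes or the list alone. The mitosis list was highest in wild type replicate 15, and without it the medians were -0.48 for mitosis and -0.29 for replication. The senescence list had 8 of 14 higher (0.16, camera adjusted p = 0.0750), with Cdkn1c the 1 member past the threshold, and p53 target genes had 20 of 26 higher (0.17, 0.103; Mdm2 at 0.68, Dcxr at 0.44).

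Genes of glycolysis and cholesterol synthesis were lower as lists, again with no member past the threshold over all genes or the list alone. Glycolysis and hypoxia genes had 19 of 23 lower (median -0.41, camera adjusted p = 3.28e-05; adjusted p = 0.487 with an estimated correlation), with Pgk1 at -1.22 and Tpi1 at -0.63. That median was -0.24 without wild type replicate 14 and -0.23 without p63 alphaKO replicate 11. Cholesterol synthesis genes had 18 of 21 lower (-0.35, camera adjusted p = 7.57e-05; adjusted p = 0.493 with an estimated correlation), with Stard4 at -0.69, Fdft1 at -0.57, and a median of -0.56 without p63 alphaKO replicate 10. Oxidative phosphorylation had 16 of 25 lower (-0.03, 0.302; Ndufa1 at -0.57, Atp5a1 at -0.34) and mitochondrially encoded genes 7 of 11 higher (0.05, 0.589; mt-Nd2 at 0.32, mt-Co1 at 0.29).

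Signalling, stress and immune lists were not called, apart from early response genes. These genes, listed as markers of cell handling, had 13 of 15 members lower (median -0.31, camera adjusted p = 0.00328, and 0.493 with an estimated correlation). Whether handling moved them was not tested. Atf3 (-1.21) had 10 to 15 reads per wild type library and 2 to 3 per p63 alphaKO library. Nr4a1 (-1.38) had 6 to 13 and 0 to 3 reads. The camera adjusted p of the list was 0.0693 without wild type replicate 14 and 0.107 without p63 alphaKO replicate 11. Lower members were in the majority for the BMP and TGF-beta pathway (11 of 16, -0.28, 0.0512; Fst at -0.86, Tgfbr2 at -0.66), FGF and EGF receptors and ligands (14 of 22, -0.03, 0.122; Fgfr1 at -1.70, Fgfr3 at -1.15), Notch (7 of 12, -0.14, 0.224; Rbpj at -0.98, Hes1), Wnt (12 of 19, -0.16, 0.330; Fzd6 at -0.53) and unfolded protein stress (16 of 20, -0.10, 0.122; Cebpb at -0.71, Atf3). Wnt10b, a Wnt ligand, had 3 reads in p63 alphaKO and 32 in wild type, a wild type to p63 alphaKO ratio of 7.70 (exact 95% interval 2.41 to 39.3). That interval covers counting error alone, and Wnt10b did not pass the threshold (limma adjusted p = 0.758). Higher members were in the majority for the interferon response (9 of 12, 0.28, 0.0886; Ddx58 at 0.77, Irf9 at 0.80), class I antigen presentation (6 of 9, 0.04, 0.450; Tap1 at 0.42, B2m at 0.25) and oxidative stress (15 of 20, 0.12, 0.381; Cbr3 at 0.52, Slc7a11 at 0.29). Wound and alarm genes had 12 of 23 higher (0.06, 0.853, with camera's direction downward; Tslp at -0.98, Slpi at 1.16). Mesenchymal and migration genes had 12 of 22 lower (-0.03, 0.736, with camera's direction upward), with Mmp9 past the threshold adjusted over the list alone and Tgfbi at -1.08.

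Markers of other cell types differed between libraries within each group. Muscle genes were the 1 such list called: 7 of 7 tested members were lower in p63 alphaKO (median -2.29, camera adjusted p = 3.35e-09; adjusted p = 0.435 with an estimated correlation), and 6 passed adjusted over the list alone. The 10 muscle genes summed to 74.2, 69.6 and 528 CPM in wild type replicates 13, 14 and 15 and to 17.4, 29.0 and 72.9 CPM in p63 alphaKO replicates 9, 10 and 11, so replicate 11 lay level with wild type replicates 13 and 14. Acta1, skeletal actin, was at 9.74, 10.57 and 122.93 CPM in wild type and 0.91, 1.67 and 4.70 CPM in p63 alphaKO, and Tnnc2, a fast troponin, stood at -2.70. Des was listed at 0 in all p63 alphaKO libraries and had 25 reads in wild type. Set at 3 reads in each p63 alphaKO library it was at least 1.92-fold lower there, and with Des at that bound the list median was -2.29. Without wild type replicate 15 the list median was -1.46. Melanocyte genes summed to 913, 835 and 353 CPM in wild type replicates 13, 14 and 15 and to 628, 1148 and 267 CPM in p63 alphaKO replicates 9, 10 and 11 (8 of 12 lower, median -0.17, camera adjusted p = 0.330; Ednrb at -1.21, Tyrp1 at -0.62). Fibroblast genes summed to 55.9, 36.7 and 17.5 CPM and to 20.6, 48.3 and 12.9 CPM in the same order (6 of 7 lower, -0.61, 0.147; Col3a1 at -1.01, Col5a1 at -1.07). Hair follicle (5 of 10 lower, -0.003, 0.330; Msx2, and Foxn1 at 0.57), sebaceous gland (3 of 5 lower, -0.002, 0.757; Scd1 at -0.38, Cidea at -0.35) and endothelial markers (2 of 3 higher, 0.43, 0.564; Pecam1 at 0.69, Flt1 at 0.43) were not called. Too few members were tested for immune and Langerhans (2), Merkel (1) and erythroid (0) markers, which summed to at most 17.4, 3.45 and 4.11 CPM in any library.

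**Figure D3:**
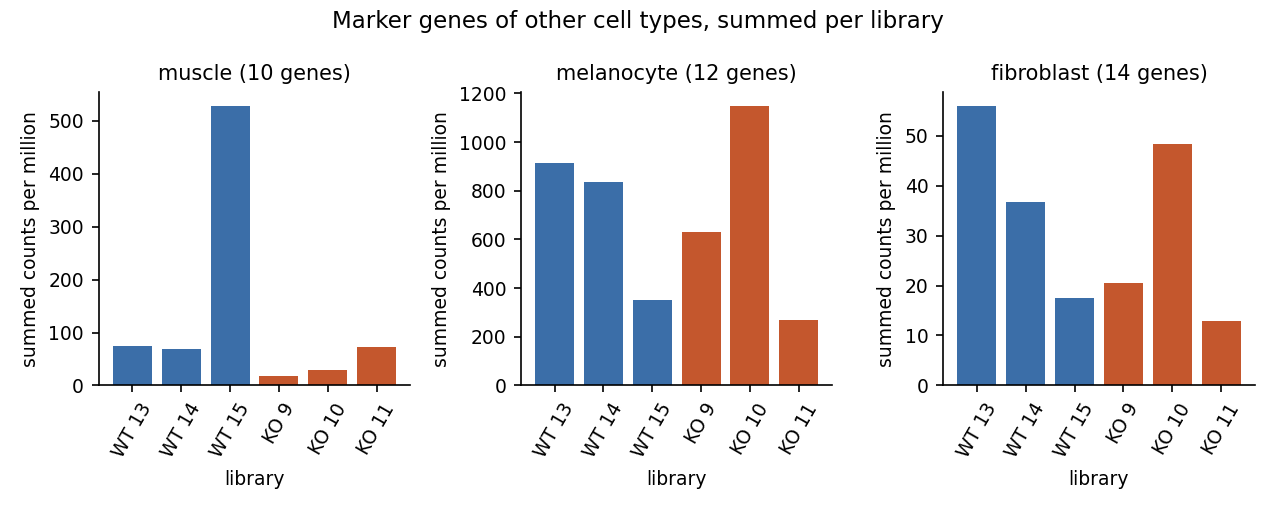
Summed CPM of the muscle, melanocyte and fibroblast marker genes in each of the 6 libraries, wild type (WT, blue) and p63 alphaKO (KO, orange), 1 bar per library from 0. Muscle genes reach 527.94 CPM in wild type replicate 15 and at most 74.16 CPM in the other libraries, and melanocyte genes are lowest in wild type replicate 15 and p63 alphaKO replicate 11.

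These libraries also stood apart as a whole. The first principal component (33.2% of the variance) set p63 alphaKO replicate 11 (61.15) and wild type replicate 15 (13.55) apart from the other 4 (-26.86 to -8.74), and the second (22.9%) separated the groups. Pearson correlations across genes were 0.923 to 0.958 within groups and 0.915 to 0.955 between them. Leaving out both libraries gave 48 genes past the threshold, 7 higher and 41 lower, among them all 5 genes above. Xist, transcribed from the inactive X chromosome, was at 290.64 CPM in wild type replicate 13 and 673 CPM in p63 alphaKO replicate 11, where Ddx3y, Uty, Eif2s3y and Kdm5d, on the Y chromosome, were listed at 0. The other 4 libraries had Ddx3y at 70.5 to 76.3 CPM, so each group held 1 library with the female pattern, and the list of sex-linked genes was not called (3 of 5 higher, median 0.06, camera adjusted p = 0.943).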

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

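Thinning to equal depth, 1 surrogate variable, the fit without both wild type replicate 15 and p63 alphaKO replicate 11, and, for the lists and Trp63 alone, the fits with no trend, robust moderation, array weights, sex as a covariate or (Trp63) DESeq2 were chosen after the results were seen. Against 5 genes past the threshold, there were 2 with a pseudocount of 0.5, 3 with 5, 1 with no filter, 2 at a mean of at least 5 CPM, 2 with sex as a covariate and 2 by edgeR. Without limma's trend there were 0 (827 at an unadjusted p under 0.05), while edgeR and DESeq2 called 2 and 18. Array weights gave 34 (9 higher), 1 surrogate variable 50 (13 higher) and the fit of 2 against 2 libraries 48 (7 higher), and each of these 3, like DESeq2, kept all 5 genes. With 1 library left out the count ran from 2 to 13, the lowest without wild type replicate 13 or 14 and the highest without p63 alphaKO replicate 11. It was 4 or 5 under quantile, equal-total and TMM scaling, robust moderation and thinning. Over 22 alternatives Krt1 missed the threshold in 1 (no trend), Cdkn1c in 3, Sncg in 10, Fut9 in 11 and Ifitm3 in 13, and none of the 5 changed sign. Against 9 lists called, camera with an estimated correlation called 0 (2 at an unadjusted p under 0.05) and fry 0 (3 at an unadjusted p under 0.05; 5 by its mixed test, which ignores direction). The range with 1 library left out was 10 to 17, with 17 without wild type replicate 15 and 15 without p63 alphaKO replicate 10, and the other alternatives gave 8 to 11. Mitosis, muscle, DNA replication, spinous and glycolysis lists lost the call only with camera at an estimated correlation and with fry. Beyond single libraries, the epidermal transcription factors also lost it with array weights (adjusted p 0.0520), 1 surrogate variable (0.0648) and 2 against 2 libraries (0.0946), early response genes at a mean of at least 5 CPM (0.185) and with 1 surrogate variable (0.0610), and in the fit of 2 against 2 the cornified envelope (0.338) and cholesterol (0.0616) lists. The cause of these moves was not tested. Trp63 stayed short of the threshold in all alternatives, with log2 fold changes of 0.11 to 0.35. At this depth low genes rest on few reads: Fut9 has 3 reads and Mmp9 1 read in wild type. DESeq2 gave no adjusted p for 231 genes.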

Other observations

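The tests of newborn muscle, of a single library, of the spinous share and of other splits for the count of genes were chosen after their results were seen, as were the lists of liver, myosin, skeletal muscle, other organs, the Cdkn1c domain and the Ifitm family. Cdkn1c rose without a called change in these genes near it: Phlda2 had a log2 fold change of -0.13 (SE 0.34), Nap1l4 of 0.13 (SE 0.22), Cd81 of 0.002 (SE 0.21) and H19 of -0.69 (SE 0.49). Whether each of them is imprinted in keratinocytes was not tested. Kcnq1ot1, the noncoding RNA whose transcription silences Cdkn1c on the paternal copy, was at 0.60 (SE 0.32, limma adjusted p = 0.807). Ifitm2, next to Ifitm3, was at 0.44 (SE 0.24, adjusted p = 0.816), and Bst2 at -0.06. Within 10 Mb of Trp63 on either side, 8 of 130 genes had an unadjusted p under 0.05, 6.15% against 6.36% elsewhere. Of 18 genes of other organs, Mbp was seen in all 6 libraries, at 47.65 to 114.16 CPM.

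Muscle genes were lower in p63 alphaKO as a list (adjusted p = 0.435 with an estimated correlation), though not in replicate 11 against wild type replicates 13 and 14, and liver genes followed them across libraries: Alb was at 17.91, 5.91 and 51.46 CPM in wild type replicates 13, 14 and 15, 0 in p63 alphaKO replicates 9 and 10 and 16.46 CPM in replicate 11, and 16 of 16 liver genes reached 1 CPM in some library. Muscle of the newborn pups is argued against, since Myh3 and Myh8, the embryonic and neonatal myosins, had 0 of 654 myosin heavy chain reads (exact upper limit 0.562%) beside 551 of Myh4, an adult form, provided that the counting covers their 3' ends. A single library is argued against as the whole cause by a median of -1.46 without wild type replicate 15. Reads spilled over from libraries of adult organs stay open as a candidate explanation, with Afp, abundant in newborn liver, holding 1.12% of the Alb and Afp reads (3 of 269, exact 95% interval 0.231 to 3.22%). A muscle or liver difference due to genotype was not tested, and 13 of the 50 genes called with 1 surrogate variable are muscle or liver genes.

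Mitosis and replication lists were lower in p63 alphaKO beside a higher Cdkn1c, a cell cycle inhibitor, although both calls were lost with an estimated correlation (adjusted p = 0.435 for each). A single library is argued against as the whole cause by a mitosis median of -0.481 without wild type replicate 15; without that library and p63 alphaKO replicate 11 the medians were -0.395 for mitosis and -0.31 for replication. In an exact count over the 10 splits of the 6 libraries, 1 (the real one, camera p = 2.49e-19) gave a mitosis p as small, the smallest of the others being 1.132e-13, and 10 splits are too few for a share under 0.05. The median of the mitosis list was -0.67 with all libraries thinned to equal depth and -0.68 without thinning. As CPM already divide by the reads of a library, thinning could hardly move this median. It does not decide on lower depth. Thinning equalizes the number of reads and nothing else. Slower division linked to genotype is a hypothesis that was not tested, as division was not measured. A difference in how dense the cultures were at harvest was not tested either, and both stay open.

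Krt1 fell and Krt10 was lower, both keratins of the first cells to leave the basal layer. The other 15 members of the spinous list had a median of -0.235 (bootstrap 95% interval -0.437 to 0.00103), above the -1 set for a loss of spinous cells. This is a median over genes, so its interval does not measure the spread between libraries. How far those members are restricted to spinous cells was not tested, and Calm4 and Lgals7 lay far above Krt10 in wild type. The median therefore does not decide the question, and a lower share of spinous cells stays open. Thinning to equal depth left the log2 fold change of Krt1 unchanged at -2.44. CPM already divide by the reads of a library, and Krt1 had at least 81 reads in each. Thinning could therefore hardly move this value, and it does not decide on lower depth. That test was read on Krt1 alone. A weaker induction of this keratin pair in p63 alphaKO cells is another hypothesis found in these data and not tested in others. Krt10 itself did not pass the threshold (limma adjusted p = 0.286).

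For the count of genes, 2 of the 10 splits called as many as the real 5. The other, which set wild type replicates 13 and 14 with p63 alphaKO replicate 10 against the rest, also called 5: Prl2c3, Cxcl5, Wfdc2, Mal and Pmel. At an unadjusted p under 0.05 the real split had 745 genes, and 3 of the 9 other splits had more, up to 1248. For lists, 7 of the 10 splits called at least the real 9, with 14 as the highest other. With 10 splits no share under 0.05 can be reached.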
